A study of Drosophila melanogaster with 8 samples.

How the data were processed

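RNAPII ChIP-seq and input libraries of S2 cells came from H1 knockdown and LacZ control cells, 2 of each kind per condition, 8 in all. Per the labels' protocols, cells were fixed with formaldehyde and chromatin was sheared by sonication. Per the submitters' processing notes, reads were aligned to dm3 with Bowtie2 2.2.2, and MACS 1.4.2, DiffBind 2.10.0 and DESeq2 were used by the authors, with no settings given. Peak and column names say MACS2, so the peak caller's version is unsettled. Per the file headers, sites were annotated with Homer.

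The deposited table holds the authors' log2 mean concentration over all libraries and per condition; how libraries were scaled is not given in the sources used here, so a fold of 0 is not a fixed reference. The authors' fold equals the difference of the 2 concentrations to within 0.01 at all 14357 entries. The authors' p-value and FDR per entry were copied, and the FDR matched a Benjamini-Hochberg adjustment over all 14357 entries to within 0.00229. The authors' call column marks exactly the entries with an unadjusted p under 0.05. Per the file headers, the peak lists give a fold enrichment ratio over input, the −log10 of p and q, and an integer score for each peak, and the table repeats a pileup signal. The −log10 p, the pileup and the score were not used here. The deposited fold enrichments describe or rank peaks only within their own list. The authors called peaks on libraries pooled per condition, per the peak names, with a lowest −log10 q of 1.30.

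The table stacks both lists, 7472 knockdown and 6885 LacZ entries. Entries overlapping by at least 1 bp were merged into 7911 loci, each represented by its entry of highest mean concentration. Of these, 6256 held peaks of both lists, 1181 of the knockdown list only and 474 of the LacZ list only. Compartments were the heterochromatic scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet, YHet, U and Uextra), chromosome 4, windows of 1 Mb at the centromeric ends of the arms, and the rest of X and of the autosomal arms. Arm ends were taken from the last site or peak, since no dm3 sequence was used here. Repeat families and gene features are those of the authors' annotation, which names a nearest gene at any distance. Of 4755 gene names, 4753 had their gene number in a Release 6 table, which was used to pair older symbols only.

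Medians have 95% percentile bootstrap intervals from 2000 draws of loci, and shares have exact Clopper-Pearson intervals; both cover neither replicate variation nor the sharing of reads between repeated sequences. Gene lists were compared by the median over 1 site per gene with 10000 random lists drawn within 10 bins of mean concentration; the percentile is a description with no p. Simulated lists were drawn from the 4755 genes after folds were shuffled over genes, with fewer random lists per comparison. Of 200 unshifted lists of 20 genes, 4.5% fell outside the middle 95%, as did 66.0% and 100% of lists shifted by 0.1 and 0.2. For lists of 10 genes these shares were 4.5%, 40.5% and 95.5%, and smaller lists were not simulated. The shuffling removes any tie of fold to concentration or between genes, so neither the matching nor lists of related genes were tested. Of 100 simulated median intervals, 96 held the true value. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

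Comparisons, lists and the naming rule were fixed before the data were examined. The rule named the 10 largest folds per direction among sites past an FDR of 0.05 (none passed), up to 4 members of each list with the smallest FDR, ties by p, any histone gene with a site (summarised by class), and the 3 sites of smallest FDR per direction in each heterochromatic compartment. The planned fit of this work across libraries was not run, since the files used hold no values per library. Alternatives concerned the FDR threshold, a minimum fold of 1, low concentration, 1 site per gene, the window size, U and Uextra, the promoter distance, the peak threshold, the overlap and the site chosen per gene. Merged loci, loci without repeats, equal numbers of peaks by compartment, the authors' unadjusted calls and sites within 1000 bp of a TSS were added after the data were seen.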

Results

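RNA polymerase II (RNAPII) occupancy was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in S2 cells, a hemocyte-like embryonic cell line of Drosophila melanogaster. Cells depleted of the linker histone H1 were compared with cells treated against LacZ, a bacterial gene that fly cells lack. The 8 libraries comprised 2 RNAPII precipitations and 2 input libraries from each condition, and each input was 10% of the chromatin. The files give 1 mean log2 concentration per condition and site and 1 pooled peak list per condition. Read depth and values per library were therefore not known here, and no spread between replicates could be computed. All folds below are differences of log2 concentration, H1 knockdown minus LacZ, from the authors' deposited table, and all positions are in dm3. The labels do not say whether the replicates came from separate cultures, so the authors' p-values measure only the spread between these libraries.

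The first comparison asked at which sites RNAPII occupancy differed after H1 depletion. Sites at the genes of the depleted histone itself, His1, had folds above 0 at all 16 entries within 1000 bp of a His1 transcription start site (TSS), with a median of 0.37 (95% bootstrap interval 0.21 to 0.51). These entries formed 11 loci of a repeated gene whose copies share nearly all their sequence, so they are not independent. For comparison, 68.2% of all entries, and 85.1% of genes at 1 site each, had a fold above 0. Occupancy of a gene by RNAPII does not measure the depletion of its transcript, so it does not check the knockdown. The smallest p of the authors' deposited table belonged to the promoter of the His1 copy His1:CG33816 on the unplaced scaffold collection Uextra, from 11151971 to 11152437, with a fold of 0.92 and an FDR of 0.0718. A second Uextra locus, from 15132677 to 15133389, had a fold of 0.82 and the same FDR in the authors' deposited table. It was annotated at a transcription termination site, and the TSS assigned to it, of an 18S ribosomal RNA copy, lay 40929 bp away. Outside Uextra, the promoter of Gld, which encodes glucose dehydrogenase (3R, 3091158 to 3091571), had a fold of 0.91 and an FDR of 0.159 in the authors' deposited table. Gld was chosen after its values were seen.

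By DiffBind, none of the 14357 entries of the authors' deposited table passed an FDR of 0.05, in either direction. The authors' own calls marked 573 entries as higher and 8 as lower, and these were exactly the 581 entries with an unadjusted p under 0.05. They made up 4.05% of all entries, where 5% are expected with no difference at any site. Each entry is 1 peak of 1 of the 2 lists, so a locus found in both lists was counted more than once. Merged by overlap, the entries formed 7911 loci, of which 403 were called higher and 8 lower. The median fold of all entries was 0.08 (95% bootstrap interval 0.07 to 0.08), with the 25th percentile at -0.03 and the 75th at 0.19, and 68.2% of all entries had a fold above 0. Folds of at least 1 in either direction occurred at 8 entries, and the 3 positive and 5 negative ones had no FDR under 0.05 in the authors' deposited table.

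**Figure D1:**
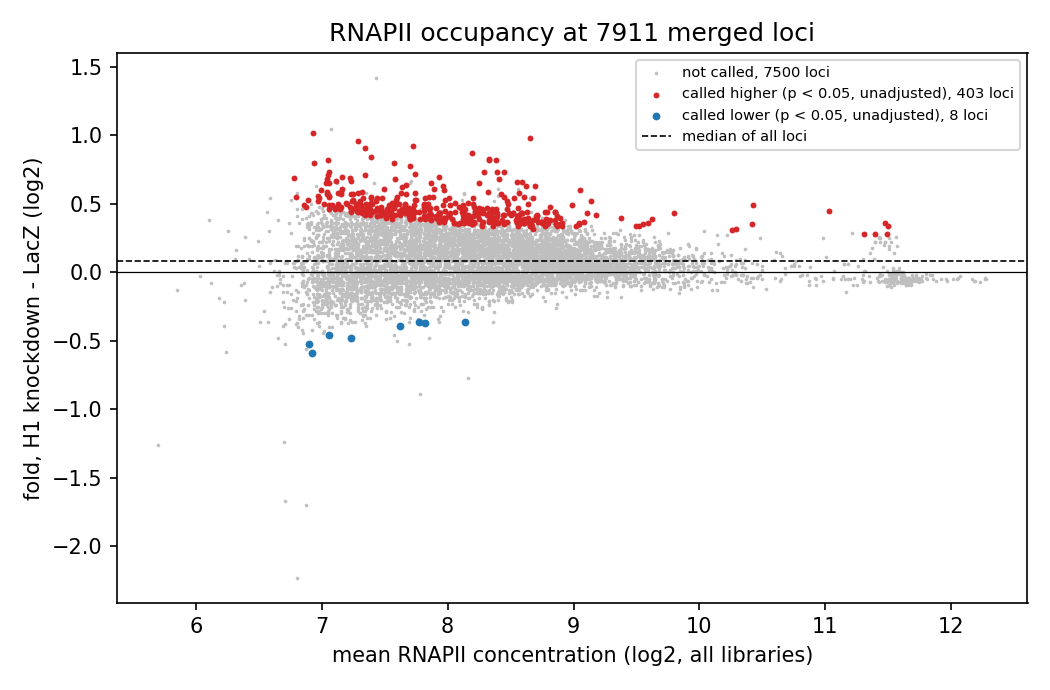
Fold of RNAPII occupancy (H1 knockdown minus LacZ, log2) against mean concentration over all libraries (log2) for 7911 merged loci, 1 point per locus. Red points are the 403 loci the authors called higher and blue points the 8 called lower at an unadjusted p under 0.05; the dashed line is the median of all loci, 0.08.

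All 8 loci called lower are named here, chosen after their values were seen. Of these, 5 carried a repeat annotation. A Gypsy6 element on 3RHet (914754 to 915116) had a fold of -0.59 and a Baggins1 element on 3LHet (835459 to 835773) one of -0.52 in the authors' deposited table. The authors' deposited table gave folds of -0.36 for an Invader6 element in an intron of Dbp80, -0.39 for a DMCR1A element near CG41284 and -0.37 for a Burdock element in an intron of pigs. The remaining 3 were an intron of CG32365 with a fold of -0.48, an intron on 2R from 3656308 to 3656581 with no gene name and a fold of -0.46, and the promoter of CG34370 with -0.36, all from the authors' deposited table. Of the 403 loci called higher, 94.3% carried no repeat annotation and 67% lay at promoters, against 66.3% and 51% of all 7911 loci.

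The series title concerns heterochromatin, so sites were next compared between chromatin compartments. Entries on the heterochromatic scaffolds had a median fold of -0.02 (-0.03 to -0.02), and those on the rest of the autosomal arms 0.12 (0.11 to 0.12). The rest of the X arm had a median of 0.14 (0.13 to 0.15). Chromosome 4, which is largely heterochromatic and yet carries active genes, had the highest median of these compartments, 0.21 (0.16 to 0.26), from 88 entries. The 1 Mb windows next to the centromeres of the arms had a median of 0.02 (-0.01 to 0.06), and windows of 2 Mb one of 0.07. These intervals are 95% bootstrap intervals over loci, which are not replicates, and do not hold the variation between libraries. No entry of any compartment passed an FDR of 0.05, so the planned Fisher test of higher against lower sites could not be computed. With the authors' unadjusted calls in its place, 94 loci on the scaffolds were called higher and 4 lower, against 220 and 3 on the autosomal arms (Fisher's exact test, two-sided, p = 0.206, adjusted p = 0.826 over 4 compartments). Only 8 loci in all were called lower, so this test could hardly detect a difference between compartments. Its p is also over loci, which are not replicates.

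The share of loci called higher was 15.7% on chromosome 4 (8 of 51 loci, exact 95% binomial interval 7.02 to 28.6%) and 7.87% in the pericentric windows (27 of 343, 5.25 to 11.2%). It was 5.36% on the autosomal arms (220 of 4102, 4.69 to 6.10%) and 3.69% on the scaffolds (94 of 2544, 3.00 to 4.50%). Of these 94 scaffold loci, 78 lay on Uextra, the unplaced collection (of 1627 loci). The others lay on 2RHet (8 of 174), 3RHet (4 of 130), 3LHet (2 of 154) and U (2 of 405). Uextra also holds histone gene copies. Within 1000 bp of a TSS there, 7 of 9 His1 and 11 of 109 core histone entries were called higher. Among loci without a repeat annotation, chromosome 4 stayed first with 20% (8 of 40, 9.05 to 35.6%). The scaffolds then had 13.5% (81 of 601, 10.8 to 16.5%) and the pericentric windows 15.1% (23 of 152, 9.84 to 21.8%). This scaffold share was not computed without Uextra, so it cannot be read as a property of the placed scaffolds. The autosomal arms had 5.83% (215 of 3689, 5.09 to 6.63%) and the rest of the X arm 7.02% (53 of 755, 5.30 to 9.08%). The share among scaffold loci with a repeat was 0.669% (13 of 1943). On chromosome 4 the sites of smallest p were an exon of ATPsynbeta, a subunit of the mitochondrial ATP synthase (fold 0.71, FDR 0.963), the promoter of asRNA:CR44030 (0.61) and the 5' UTR of the adaptor gene Crk (0.42), from the authors' deposited table. The negative sites of smallest p there were repeats in or near ey (-0.20), lncRNA:CR43437 (-0.12) and CG32850 (-0.06) in the authors' deposited table. In the pericentric windows the authors' deposited table placed first an exon of light (lt), a vacuolar sorting gene that resides in heterochromatin, at 22817480 to 22818081 of 2L, with a fold of 0.60 and an FDR of 0.835. It was followed by introns of Stlk (0.49) and CG17698 (0.58) in the authors' deposited table. Negative pericentric sites of smallest p lay near lncRNA:CR43242 (-0.31), CG17493 (-0.36) and CG43968 (-0.36), again from the authors' deposited table. On the scaffolds the positive site of next smallest p after the 2 above was on Uextra from 18013593 to 18014014 (fold 0.96, FDR 0.128 in the authors' deposited table).

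Within every compartment, loci with a repeat annotation had a lower median fold than loci without one. On the autosomal arms the medians were -0.05 (-0.05 to -0.04, 413 loci) with and 0.15 (0.14 to 0.15, 3689 loci) without a repeat, and on the scaffolds -0.03 (-0.04 to -0.03, 1943 loci) and 0.09 (0.07 to 0.11, 601 loci). The annotation names a repeat only in introns and between genes, so loci without one include all promoters. Within introns and intergenic regions of the arms, the median was -0.05 (-0.05 to -0.04) for 715 repeat loci and 0.10 (0.05 to 0.14) for 230 others. Promoter loci had medians of 0.16 (0.16 to 0.17) on the arms, 0.15 (0.10 to 0.21) on the scaffolds and 0.27 (0.24 to 0.33) on chromosome 4.

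**Figure D2:**
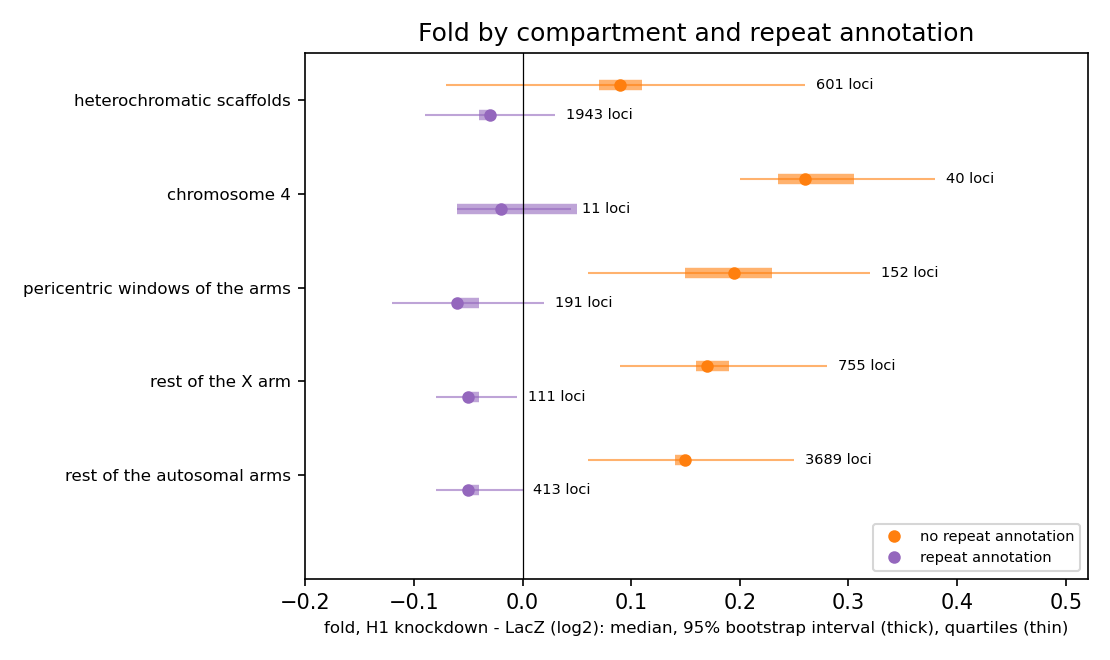
Median fold (log2, H1 knockdown minus LacZ) of merged loci in 5 chromatin compartments, split by repeat annotation; points are medians, thick bars 95% bootstrap intervals over loci and thin bars the range from the 25th to the 75th percentile. The medians of repeat loci lie between -0.06 and -0.02 and those of other loci between 0.09 and 0.26. On the scaffolds the thin bars overlap (-0.09 to 0.03 with and -0.07 to 0.26 without a repeat).

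Of the 24 repeat families with at least 30 loci, all had a median fold below that of all loci, 0.08, and 19 had a 95% bootstrap interval wholly under 0. The LTR retrotransposon families Nomad (-0.11, -0.13 to -0.10, 43 loci) and Burdock (-0.09, -0.13 to -0.07, 47 loci) and the LINE family J1 (-0.09, -0.10 to -0.07, 86 loci) had the lowest medians. The most numerous, DM176 with 307 loci, had a median of -0.04 (-0.04 to -0.03). Copia was the only one of the 24 with its interval above 0, with a median of 0.07 (0.04 to 0.09, 161 loci), and Mdg3, at 0.03 (-0.02 to 0.07, 87 loci), held 8 of the 13 loci called higher in these families. Reads of repeat copies may not be placed uniquely, which was not measured here, so loci of a family cannot be taken as independent. Families were grouped after the files were seen.

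**Figure D3:**
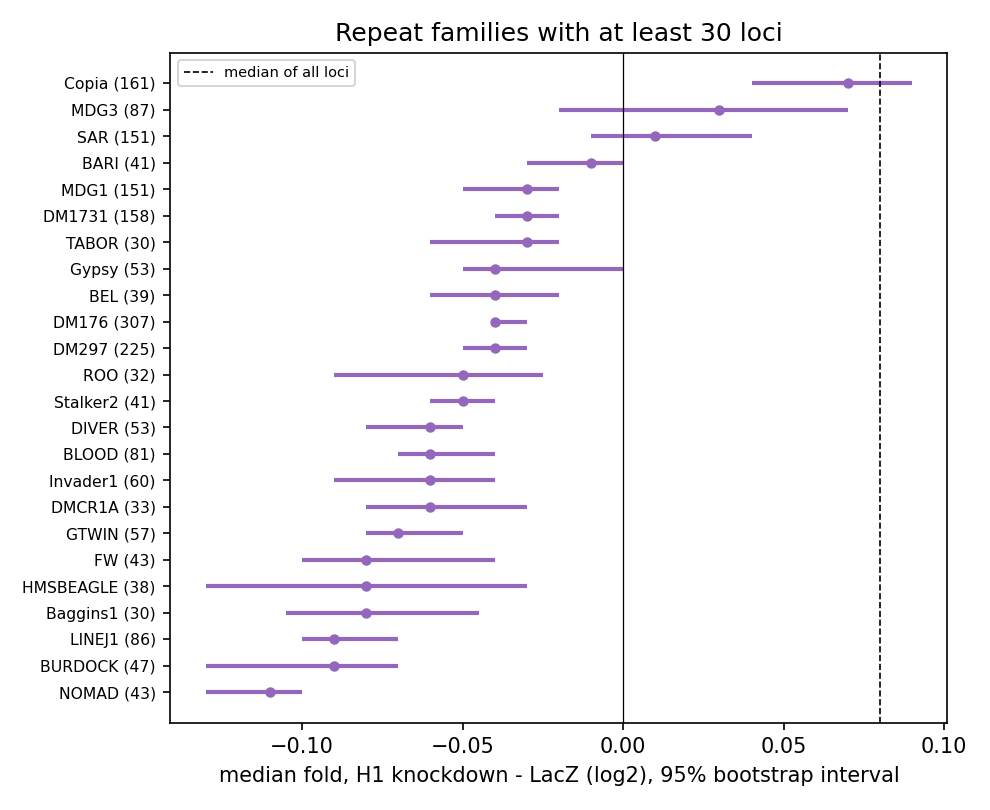
Median fold (log2, H1 knockdown minus LacZ) of merged loci for the 24 repeat families with at least 30 loci, the number of loci in brackets; bars are 95% bootstrap intervals over loci and the dashed line is the median of all loci. Medians run from -0.11 for Nomad to 0.07 for Copia.

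By the authors' annotation of gene features, 7442 promoter entries had a median fold of 0.15 (0.14 to 0.15). Introns had a median of -0.03 (-0.03 to -0.03, 3633 entries) and intergenic regions one of -0.04 (-0.04 to -0.03, 2328 entries). Without repeat loci the medians were 0.08 (0.03 to 0.11) in introns and 0.025 (-0.02 to 0.06) between genes. Medians were 0.17 in exons (0.12 to 0.21), 0.12 in 5' UTRs (0.09 to 0.15) and 0.10 at transcription termination sites (0.08 to 0.13). With every site up to 500 bp from a TSS counted as a promoter, exons and termination sites each had a median of 0.01, and 5' UTRs one of 0.08. Again no entry of these classes passed an FDR of 0.05. The authors' unadjusted calls marked 367 promoter entries as higher and 1 as lower, against 32 and 1 between genes and 118 and 6 in introns. On the arms the promoters of smallest p after Gld, chosen after their values were seen, were those of lncRNA:CR45433 (fold 0.66, FDR 0.342), the GTPase gene Ns3 (0.68, FDR 0.369) and the formin gene DAAM (0.61, FDR 0.645) in the authors' deposited table. The promoters of CG8086 (0.71), the apical polarity gene crb (0.55) and the ubiquitin hydrolase gene Uch (0.80) came next in the authors' deposited table.

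The replication-dependent histone genes form a tandem array on arm 2L. The 78 entries assigned to it ran from 21401163 to 21554306, and those at both ends lay up to 15544 bp from the nearest TSS. All 78 had a fold above 0, with a median of 0.22 (0.19 to 0.25) and a range of 0.05 to 0.51. The authors called 13 of them higher at an unadjusted p under 0.05. The end entries included the lowest fold, 0.05, and called entries with folds of 0.44 and 0.45. Of entries within 1000 bp of a TSS on 2L, 1 of 7 at His1 and 8 of 53 at core histones were called higher. Within 1000 bp of a TSS on 2L the median was 0.24 for His1 (0.14 to 0.43, 7 entries), 0.23 for His2A (8 entries), 0.22 for His2B (34 entries), 0.17 for His3 (4 entries) and 0.20 for His4 (7 entries). On Uextra, 9 His1 entries had a median of 0.47 (0.27 to 0.58) and 109 core histone entries one of 0.18 (0.16 to 0.22). With 1 site per gene, the smallest p on 2L was at His1:CG33858 (21526500 to 21527133, fold 0.51, FDR 0.963), followed by the promoter of His2A:CG33853 (0.36), both in the authors' deposited table. Outside the array, the authors' deposited table gave folds of 0.29 for His3.3A, 0.16 for His3.3B, 0.13 for His4r and 0.00 for the variant gene His2Av. Copies of the array share nearly all their sequence and wide entries can span several genes, so these entries are not independent measurements.

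**Figure D4:**
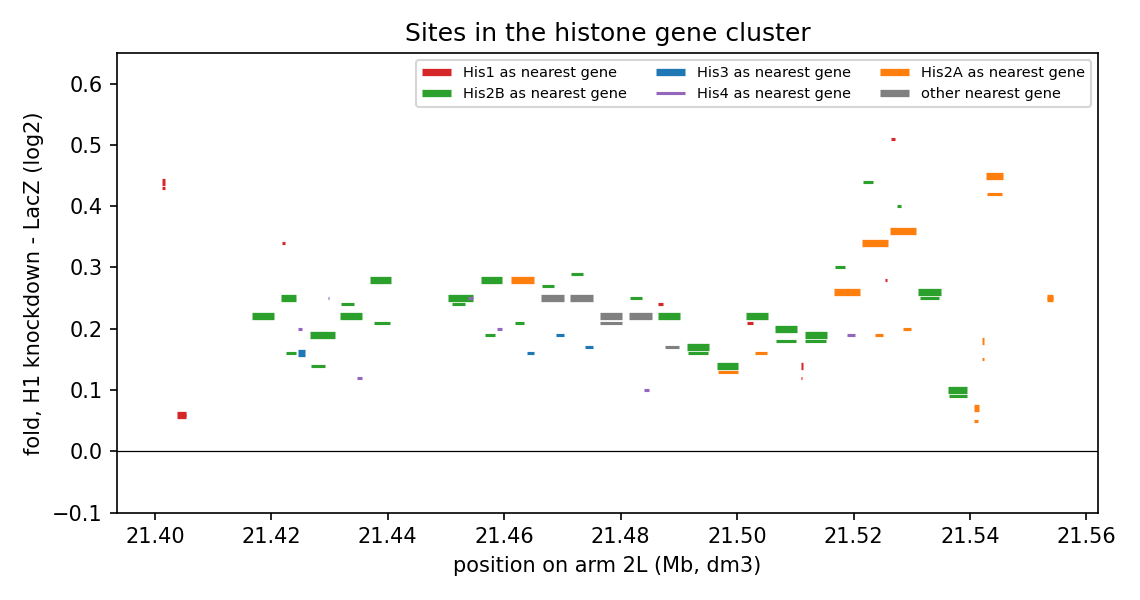
Fold (log2, H1 knockdown minus LacZ) of the 78 entries in and beside the histone gene array on arm 2L (position in Mb, dm3). Each bar spans 1 entry, thick for peaks of the knockdown list and thin for the LacZ list, coloured by the nearest annotated histone gene. Entries at both ends lie up to 15544 bp from the nearest TSS. All bars lie above 0, between 0.05 and 0.51.

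The 19 gene lists were compared by 1 site per gene, the one with the highest mean concentration, over 4755 genes whose median fold was 0.14, and 85.1% of these genes had a fold above 0. With these sites, no list had a member past an FDR of 0.05, over all entries or adjusted over the list alone. With the site closest to the TSS, histone genes and heterochromatin-resident genes each had 1 member under 0.05 when adjusted over the list alone, and 0 over all entries. The median of 2 lists lay outside the middle 95% of 10000 random lists of the same size matched on concentration, where 5% of lists do so by chance. Histone genes had a median fold of 0.16 over 89 genes, above all random lists (percentile 100). Of these genes, 33 were represented by a site more than 1000 bp from their TSS. Most are copies that share sequence, some with overlapping chosen sites, whereas random lists draw separate genes. The random range is therefore likely too narrow for this list, and the percentile can overstate how unusual it is. With the mean fold of all sites of each gene, the median of the histone list was 0.08 and lay within the random range (percentile 79.5). The 4 of smallest p were His1:CG33858, His2A:CG33853, His1:CG33804 (0.39) and His2A:CG33832 (0.45), from the authors' deposited table, the last at a repeat 5990 bp from the TSS.

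Genes that reside in heterochromatin had a median of -0.02 over 23 genes (percentile 0.05), with 11 above 0. For 16 of the 23 the chosen site lay more than 1000 bp from the TSS, and for 12 it carried a repeat annotation. With the site closest to the TSS the median was 0.24 and the percentile 99.8, so the direction turned with the choice of site. Members of smallest p in the authors' deposited table were rolled (rl), the MAP kinase gene (fold 0.42), the catenin gene p120ctn (0.42), the G protein gene cta (0.35, 14149 bp from the TSS) and the cohesin loader gene Nipped-B (0.32), all with an FDR of 1.

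RNAPII subunit and elongation factor genes had a median fold of 0.26 over 23 genes (percentile 97.1), with 22 above 0. Among them, Cdk9, the kinase that releases paused polymerase, and spt4 each had 0.39, Gdn1 0.31 and atms 0.32 in the authors' deposited table. Nuclear exosome and RNA decay genes had a median of 0.30 over 6 genes (percentile 95.5), with Cbp20 at 0.32, the exosome nuclease gene Rrp6 at 0.31, Csl4 at 0.30 and Mtr4 at 0.29 in the authors' deposited table. RNA interference genes had 0.27 over 6 genes (percentile 91.2), all above 0: Dcr-1 0.42, Dcr-2 0.34, AGO1 0.26 and Hen1 0.27 in the authors' deposited table. All 13 heterochromatin factor genes had a fold above 0, with a median of 0.18 (percentile 90.6); ADD1 had 0.33, ocm 0.28, the gene of HP1a 0.27 and Kdm4A 0.25 in the authors' deposited table. None of these named genes had an FDR under 1.

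Cell cycle and replication genes had a median of 0.14 over 19 genes (percentile 25.8; Cdk1 0.34, RnrL 0.37, E2f2 0.33 and CycA 0.23 in the authors' deposited table). DNA damage response and cell death genes had 0.13 over 14 genes (percentile 23.1; rad50 0.30, mei-41 0.28, spn-A 0.24 and Ku80 0.21 in the authors' deposited table). For hnRNP and RNA binding protein genes the median was 0.10 over 17 genes (percentile 60.1), from -0.44 at the promoter of smooth (sm) to 0.26 at hfp, with HnRNP-K at 0.24 and x16 at 0.18 in the authors' deposited table. Cytosolic ribosomal protein genes had 0.10 over 74 genes (percentile 77.3), 72 of them above 0, led by RpS14b at 0.35, RpL34a at 0.30, RpL35A at 0.28 and RpL38 at 0.24 in the authors' deposited table. Glycolysis genes had 0.10 over 11 genes (percentile 36.6; Pgk 0.29, Gapdh1 0.19, Pgi 0.19 and Pglym78 0.17 in the authors' deposited table). Heat shock and chaperone genes had 0.08 over 18 genes (percentile 31.7), and among them Hsp23 had 0.50, Hsp27 0.19, Hsp68 0.14 and Hsp22 0.14 in the authors' deposited table.

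Small nuclear and nucleolar RNA genes had a median of 0.05 over 51 genes (percentile 7.17), with snoRNA:Psi18S-301 at 0.87, snRNA:U5:14B at 0.65, snRNA:U5:38ABa at 0.48 and snRNA:U5:23D at 0.35 in the authors' deposited table. Innate immunity genes had 0.06 over 22 genes (percentile 9.76; PGRP-SA 0.26, dome 0.13, PGRP-LA 0.17 and the antifungal peptide gene Drs -0.19 in the authors' deposited table). Ecdysone response genes had 0.05 over 14 genes (percentile 4.21; usp 0.25, ftz-f1 0.18, Eip74EF 0.16 and Hr3 0.16 in the authors' deposited table). Hemocyte markers, the lineage of S2 cells, had 0.03 over 12 genes (percentile 2.19, at the edge of the random range), with PPO3 at 0.23, vkg at 0.14, crq at 0.10 and ItgaPS4 at 0.11 in the authors' deposited table. Markers of other lineages were few among the sites. Germline markers had a median of 0.10 over 6 genes (percentile 8.07; krimp 0.53, orb 0.33, bam 0.13 and AGO3 -0.20 in the authors' deposited table). The AGO3 site was an intergenic repeat more than 1000 bp from the TSS. Neuronal markers had -0.02 over 5 genes (percentile 3.70; elav 0.13, unc-13 0.12, fne -0.07 and nrv3 -0.17), and muscle markers 0.04 over 5 genes (percentile 9.53; Act57B 0.42, Tm1 0.04, Mef2 0.04 and Mhc -0.36), from the authors' deposited table. The sites of unc-13, fne, Act57B and Mhc lay more than 1000 bp from the TSS, those of unc-13 and fne at repeats. With only sites within 1000 bp of the TSS, the median was 0.13 over 3 neuronal genes and 0.04 over 2 muscle genes.

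**Figure D5:**
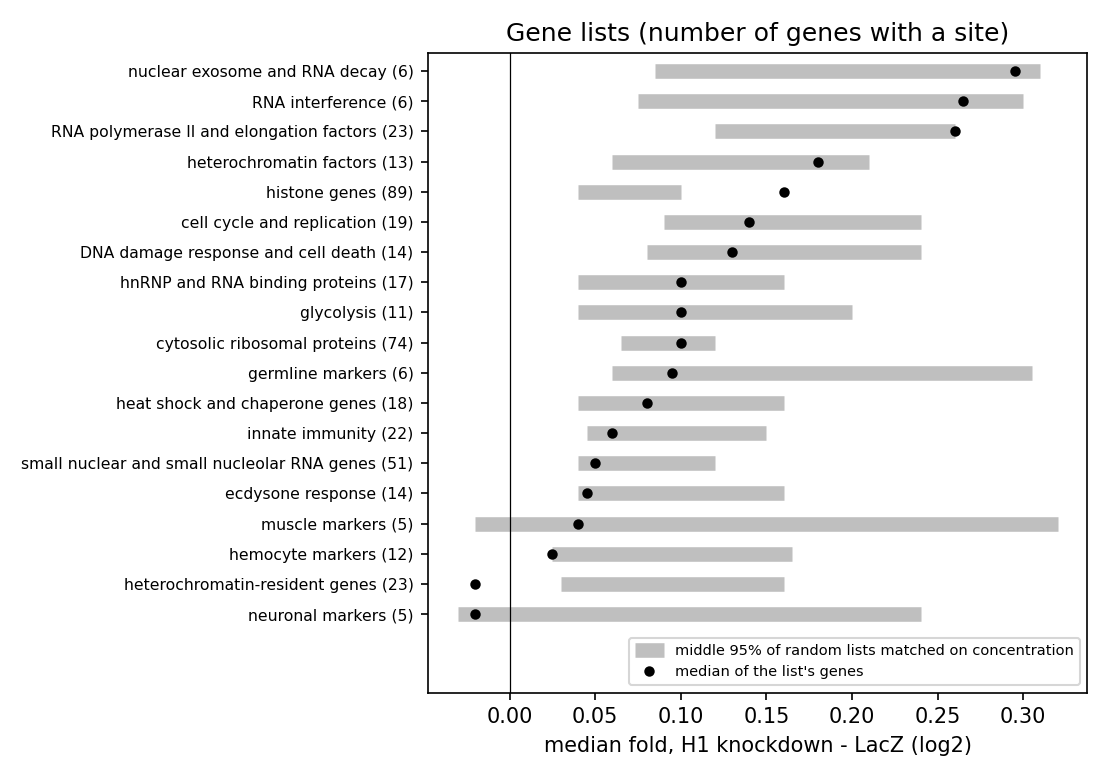
Median fold (log2, H1 knockdown minus LacZ) of 19 gene lists, 1 site per gene, the number of genes in brackets; grey bars span the middle 95% of 10000 random lists of the same size matched on concentration. Histone genes (0.16) lie above their bar and heterochromatin-resident genes (-0.02) below theirs. Copies of the histone genes are not independent, so the bar of that list is likely too narrow.

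The pooled peak lists asked which regions were called bound in each condition. The knockdown list held 7472 peaks covering 5.34 Mb and the LacZ list 6885 peaks covering 4.75 Mb, with median widths of 526 and 503 bp. Of the knockdown peaks 84.2% (exact 95% binomial interval 83.3 to 85%) overlapped a LacZ peak by at least 1 bp, and 93.1% (92.5 to 93.7%) of the LacZ peaks overlapped a knockdown peak. With as many peaks taken from each list, the shares were 85.8% and 87.8%. Peaks found in 1 list only were weaker within their list: the authors' median fold enrichment over input was 2.13 for 1181 unshared against 4.36 for shared knockdown peaks, and 1.56 for 474 unshared against 3.23 for shared LacZ peaks. Peaks were called on pooled libraries, so no test between replicates was possible, and the lengths of the lists depend on depth, which was not known here.

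Unshared peaks were spread unevenly over the genome. On chromosome 4, 14 of the 51 knockdown peaks were absent from the LacZ list (27.5%, 15.9 to 41.7%), and 0 of the 37 LacZ peaks were absent from the knockdown list (upper bound 9.49%). On the autosomal arms 16.8% (15.7 to 18.0%) of the knockdown peaks and 3.60% (3.01 to 4.27%) of the LacZ peaks were unshared, and on the rest of the X arm 20% (17.4 to 22.9%) and 3.52% (2.29 to 5.15%). On the heterochromatic scaffolds the shares were 11.9% (10.6 to 13.3%) and 12.1% (10.8 to 13.5%), and in the pericentric windows 16.9% (12.8 to 21.6%) and 13.7% (10.1 to 18.1%). With as many peaks from each list, a choice made after the data were seen, 21.5% of the LacZ and 8.38% of the knockdown peaks on the scaffolds were unshared, against 28.1% and 12.7% in the pericentric windows, 6.04% and 15.9% on the autosomal arms and 5.63% and 19.3% on the rest of X. The scaffolds held 30.5% (29.5 to 31.6%) of the knockdown peaks and 33.5% (32.4 to 34.7%) of the LacZ peaks. Intervals are exact 95% binomial intervals over peaks.

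The table and the peak lists come from the same libraries, so their comparison is descriptive. Of the 1181 unshared knockdown peaks, 90.0% (88.2 to 91.7%) had a fold above 0, with a median of 0.26 (0.25 to 0.28), and 180 were called higher. Of the 474 unshared LacZ peaks, 96.0% (93.8 to 97.6%) had a fold below 0, with a median of -0.16 (-0.18 to -0.16), and 6 were called lower. When shared peaks had to overlap by at least 50% of both, the shares were 85.3% and 67.9%.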

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

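The test of a single scaling offset was set down before its result was seen, but with the quartiles of the fold and the split of the authors' calls already known; its repeats on loci in both lists and the tests of enrichment, of repeat copies and of His1 against core histones were chosen after the results were seen. Peaks on the mitochondrial genome, which enter the totals but none of the compartments compared, were called in 1 condition only. The knockdown list held 5 peaks on the mitochondrial genome and the LacZ list 0. Their folds in the authors' deposited table ran from 0.10 to 0.21 with no FDR under 1. Their median fold was 0.15, against 0.12 for entries on the rest of the autosomal arms. The widest spanned 4094 bp. Its log2 mean concentration was 11.35 in the knockdown and 11.25 in LacZ, so signal was present in both conditions.

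The first pattern is the imbalance of the authors' unadjusted calls, 573 higher against 8 lower (212 against 0 at or above the median concentration). A single scaling offset between the conditions would leave equal tails around the median fold only if the remaining differences were symmetric. The ratio over all loci was 2.07 (481 at least 0.3 above, 232 below, 95% interval 1.77 to 2.44), above the bound of 1.5 set for it. Peaks found in 1 list only weigh on those tails, but over the 6256 loci in both lists the ratio was 2.49 (1.89 to 3.32). Both go against an offset with symmetric differences around it. Repeat and other loci, however, had different medians (-0.04 and 0.15), and such a mixture can also make tails unequal. Without repeat loci the ratio over loci in both lists was 1.56 (1.11 to 2.2), which includes the bound of 1.5. At a distance of 0.2, the ratios over loci in both lists were 1.73 with and 1.52 without repeat loci. An offset therefore stays open for loci in both lists without a repeat annotation. Of the 403 loci called higher, 180 were found in the knockdown list only, and no ratio was computed for such loci alone. A higher share of enriched fragments in the knockdown precipitations would raise the fold most at the most enriched loci. Loci were ranked by enrichment into 10 bins. The median fold of bin 10, the strongest, differed from that of bins 4 to 7 by -0.10 (-0.11 to -0.09), against that explanation as it was stated. From bin 1 to bins 5 and 6, however, the median rose from -0.06 to 0.16, as that explanation has it. The test therefore does not exclude an unequal efficiency. Unequal efficiency, alone or with scaling, differences in depth, and an effect of H1 depletion itself remain open, since no values per library were at hand.

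The second pattern is the lower folds on heterochromatic scaffolds. Weaker enrichment as the whole cause is argued against, since among loci present in both lists the scaffolds still differed from the arms by -0.13 (-0.14 to -0.12) within these 10 bins, although not in bin 1 (-0.05 on scaffolds, -0.07 on arms) and little in bin 10 (0.03 and 0.05). Reads shared between repeat copies, or another property of repeats, remain candidate explanations: in introns and between genes of the arms, outside the scaffolds, repeat loci differed from other loci by -0.15 (-0.19 to -0.10). On the scaffolds, the same regions had medians of -0.03 (-0.04 to -0.03, 1943 repeat loci) and 0.03 (0 to 0.07, 437 others). The gap was smaller there, and these other loci had a lower median than those of the arms, 0.10. The limit to introns and intergenic regions was set after a difference of -0.20 over all features had been seen. That test does not separate the placement of reads from RNAPII occupancy of repeats that truly differs from that of other introns and intergenic regions, and the biological explanation by H1 depletion stays open.

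The third pattern is the place of histone gene sites among the smallest p. Template DNA of a His1 interference reagent carried into the libraries could add reads at His1 alone. His1 entries exceeded core histone entries by 0.18 in the median (0.03 to 0.32), which lies between the bounds of 0.15 and 0.3 set for it. This explanation therefore stays undecided with 16 His1 entries at 11 loci. The medians were 0.47 for His1 and 0.18 for core histones on Uextra, and 0.24 and 0.21 on 2L, where core entries had a median width of 2588 bp and 5 of 53 overlapped a His1 entry. Core entries on 2L can therefore hold His1 sequence, which limits the comparison there, and a rise in RNAPII at histone genes after H1 depletion was not tested separately.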

How the results depend on the processing

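No paired analysis was possible because the files used hold no value per library. For the same reason the alternatives of this work's own fit were not run: size factors, library size, the low-count filter, pseudocounts, a block on the replicate number, and leaving out each library. Depth per library was not known, so what it limits could not be measured. A median or share counted as kept within its main 95% interval, a count within 1.5 times, and a gene list on the same side of its random range. For the main results 57 alternatives kept the value, 36 moved it, 9 gave more sites past a threshold and 3 changed its sign. For the others 53 were counted as kept, 10 moved it, 8 placed a list outside its random range, 1 placed a list within it and 3 were counted as a change of sign. The cause of the differences below was not tested unless stated. The median fold of 3 sets changed sign on loci without a repeat annotation, a choice made after the data were seen: heterochromatic scaffolds to 0.09, introns to 0.08 and intergenic regions to 0.025. With the same loci the median was 0.26 on chromosome 4, 0.20 in the pericentric windows, 0.17 on the rest of X, 0.15 on the rest of the autosomal arms and 0.16 at promoters. The heterochromatin-resident list changed sign with the site closest to the TSS (0.24), the mean of all sites (0.0675) and only sites within 1000 bp of the TSS (0.28). The neuronal marker list (-0.02) also changed sign, with the mean of all sites (0.0867) and only sites within 1000 bp of the TSS (0.13). It was counted as kept because it stayed within its random range.

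At an FDR of 0.1, 3 entries passed, all 3 higher and on the scaffolds. At the authors' unadjusted p under 0.05, 573 were higher and 8 lower, and 162 of these lay on the scaffolds, 9 on chromosome 4, 41 in the pericentric windows, 68 on the rest of X and 301 on the rest of the autosomal arms; these counts are larger because the threshold is looser. The authors' calls numbered 212 higher and 0 lower at or above the median concentration, and 283 and 2 with 1 site per gene, as fewer entries remain. Without U and Uextra the scaffold median was -0.04. At or above the median concentration it was -0.01, with 0.09 on X, 0.08 on the autosomal arms, 0.10 at promoters and 0.08 in 5' UTRs. Pericentric windows of 2 Mb gave a median of 0.07, and 8.22% of the knockdown and 9.24% of the LacZ peaks, as wider windows hold more peaks. On merged loci the autosomal median was 0.13. With sites up to 500 bp from the TSS called promoters, the median was 0.01 at termination sites, 0.08 in 5' UTRs and 0.01 in exons.

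Shared peaks made up 80.2% of the knockdown and 87.1% of the LacZ list with an overlap of at least 50% of both, 80.8% and 87.7% with summits within 200 bp, and 85.8% and 87.8% with as many peaks from each list. They made up 83.3% and 95.7% at a −log10 q of at least 10, and 94.4% of the LacZ list at 5. The scaffolds then held 27.5% of the knockdown and 30.2% of the LacZ peaks at 10, and the pericentric windows 3.23% and 3.52%, with 3.95% of the LacZ list at 5. Unshared peaks with a fold in their own direction made up 85.3% (knockdown) and 67.9% (LacZ) with the overlap of 50%. Lists outside the middle 95% numbered 5 with the site closest to the TSS. Besides histone and heterochromatin-resident genes, these were RNAPII and elongation genes (median 0.26, percentile 98.6), neuronal markers (-0.02, 1.65) and ecdysone response genes (0.05, 2.04). They numbered 2 with the mean of all sites, RNAPII and elongation genes (0.27, percentile 99.0) and hemocyte markers (0.03, 1.88), and both lists outside in the report fell within, histone genes at 0.08 (percentile 79.5). With only sites within 1000 bp of the TSS they numbered 5. Histone genes (0.20) and heterochromatin-resident genes lay above, and hemocyte markers (0.01, percentile 0.065), ecdysone response genes (0.05, 0.32) and small nuclear and nucleolar RNA genes (0.05, 0) below. In this setting too, histone and heterochromatin-resident genes each had 1 member under 0.05 adjusted over the list alone.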

Other observations

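The test of clustering below was set down before its result was seen; the other values here were chosen after the data were seen. Of the 10 loci with an FDR under 0.2 in the authors' deposited table, 9 lay on Uextra and 1, the Gld promoter, elsewhere, and all 10 had a fold above 0. The single most negative fold was -2.23 at a LacZ peak on Uextra (8133414 to 8133786; p = 0.121 in the authors' deposited table), and the highest was 1.42 in an intron of mus301 (3L, 8133191 to 8133619; p = 0.0765 in the authors' deposited table).

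Loci present in both lists were ranked by the authors' enrichment within each list and split into 10 bins. Arm loci had a median of -0.07 in bin 1, the weakest, 0.21 in bin 4 and 0.05 in bin 10. Scaffold loci of the same bins had medians of -0.05, -0.02 and 0.03. The satellite class had a median of 0.01 (-0.01 to 0.04, 168 loci), the LINE class -0.07 (-0.07 to -0.05, 389 loci) and the LTR class -0.04 (-0.04 to -0.04, 2026 loci).

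One hypothesis was that loci called higher cluster along the arms, as they might if H1 loss acted on domains. Among 4596 non-repeat arm loci, 291 were called higher, and 21 of these had a called locus as nearest neighbour, against a median of 18 in 10000 random draws within arms (middle 95% of draws 9 to 29). The number of neighbouring pairs was therefore within the range of random draws, and the hypothesis was not borne out. Without histone genes, a check added after that result, the number was 19 against a middle 95% of 8 to 28.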
